A study of Homo sapiens with 3 samples.

How the data were processed

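RNA sequencing was carried out on Cal-33 cells, an established human tongue squamous cell carcinoma line. Cells were transfected with a small interfering RNA (siRNA) and harvested 72 h later. Per the labels, 3 libraries were made, each from cells given a different siRNA: a control siRNA (siControl), an siRNA against p53 (sip53) and an siRNA against BACH1 (siBACH1). There was 1 library per group. Total RNA was extracted with a column kit and libraries were made with a SMARTER mRNA kit, per the labels' protocols. Strand handling is not given in the sources used here.

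The authors deposited 1 table of TPM (transcripts per 1000000) with 28890 genes and a column per library. The submitters' processing notes name bcl2fastq 2.20, which converts base calls to reads, and kallisto 0.44.0, which assigns reads to transcripts by pseudoalignment and estimates their abundance. The notes name GRCh38, GRCm38 and mm10 without a role for each. The last pair are mouse builds, while the table lists human gene symbols. The transcript annotation and the way transcripts were summed to genes are not given in the sources used here. Of the 28890 symbols, 28817 matched a symbol or synonym of the RefSeq gene table. The table held 19259 protein-coding genes, 9034 pseudogenes and 597 genes of other kinds or without a match. The listed values summed to between 978371 and 979148 per library, so 2.09% to 2.16% of the total of 1000000 belonged to entries not listed. TPM keeps no depth, so the number of reads behind each value is unknown, and no counting interval or detection limit is given. Pseudoalignment divides reads among near-identical copies, so values of paralogs, pseudogenes and read-through transcripts are uncertain.

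Each pair of libraries was compared as log2((TPM + 1)/(TPM + 1)), with a pseudocount of 1.0 TPM that understates the change of weakly expressed genes. A fold given with TPM values is the plain ratio of TPM. Genes with TPM of at least 1.0 in 1 or both libraries counted as measured. Genes were counted at a 2.0-fold difference. With 1 library per group there was no replicate check, so no test, standard error or p-value is given, and all values describe these 3 libraries. The comparisons were p53 knockdown against control, BACH1 knockdown against control, and BACH1 knockdown against p53 knockdown.

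The samples, comparisons, gene lists, rule for naming genes and most alternatives were fixed before the data were examined. Named genes were the targeted genes and, for each knockdown, the 12 genes with the largest and the 12 with the smallest log2 change among genes with TPM of at least 5.0 in 1 or both libraries. Symbols of clones, LOC numbers, small RNAs, mitochondrial genes and ribosomal pseudogenes were left out of these. Up to 4 members with the largest absolute change were named for each gene list, among members with TPM of at least 1.0 in 1 or both libraries. Over both knockdowns, the rule took the 8 genes (TPM of at least 5.0 in 1 or more libraries) with the largest smaller absolute change in the same direction, per direction, and the 8 with the largest smaller absolute change in opposite directions. A few further list members are named as examples chosen after their values were seen, and are marked as such. Some genes taken by the rule are not reported here.

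The 29 gene lists covered BACH1-repressed antioxidant, heme and iron genes, BACH1-linked invasion and glycolysis genes, other NRF2-responsive genes, ferroptosis defence and promotion, heme synthesis, canonical p53 targets, G1/S and DNA replication, G2/M cell cycle, mesenchymal and matrix genes, epithelial junction, basal squamous and squamous differentiation genes, matrix proteases, TGF-beta response, YAP/TEAD targets, ATF4 stress response, ER chaperones, heat shock, interferon-stimulated genes, inflammatory cytokine and NF-kappaB genes, cholesterol synthesis, hypoxia and glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded genes, cytosolic ribosomal proteins, reference genes, and markers of fibroblasts and of immune and endothelial cells. Several lists share members. Each list was summarised by its measured members at least 1.5-fold higher or lower, its median log2 change, and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with at least 5 measured members were given a percentile. A list was said to stand apart where the percentile was under 2.5 or over 97.5.

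The correlation of the 2 knockdown responses was set beside 100 simulations of unchanged libraries that share a control library, because a shared control alone correlates them. The alternatives fixed at the start were a pseudocount of 0.1 or 5 TPM, no filter or a minimum of 5 TPM, TPM rescaled to a median ratio of 1 to the control (factors of 0.950 for sip53 and 0.945 for siBACH1), TPM recomputed without 13 mitochondrially encoded and 88 cytosolic ribosomal protein genes, thresholds of 1.5-fold and 3-fold, and random lists not matched on expression. Alternatives added after seeing the data were protein-coding genes only and a log2 change corrected for transcript GC content and length. For the correction, 1 transcript per gene was taken from GENCODE 29 (the longest protein-coding, otherwise the longest), which gave a value for 97.8% of the measured genes. Running medians over 20 bins of GC content and then of length were subtracted. Gene positions are those of GENCODE 29 on GRCh38.

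The steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were first tested on a simulated pair of libraries drawn from the control profile, with 12258 genes and a noise SD of 0.20 on the log2 scale. At the 2.0-fold threshold, 99.0% of 100 genes altered 3-fold and 100.0% of 100 genes altered 4-fold were recovered, and 0 of 12058 unaltered genes were counted. The altered genes had at least 5 TPM in the control, and the noise was the same at every expression level. The real log2 changes had SDs from 0.29 to 0.33. The simulation therefore checks the steps and gives no rate of false counts for the real libraries. Of 200 random lists of 20 genes, 3.50% fell outside the central 95% of random lists, and 96.0% of lists raised by 0.20 were found. All columns of the table were used.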

Results

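The transcriptome of Cal-33 cells was measured in 3 libraries, 72 h after transfection of a control siRNA, an siRNA against p53 or an siRNA against BACH1. Cal-33 is a human tongue squamous carcinoma line. BACH1 is a heme-responsive transcriptional repressor, and p53 is a transcription factor of the DNA damage response. There was 1 library per group, so no difference given here has a replicate check. Between 12113 and 12198 genes reached 1 TPM in each library, and the depth behind them is unknown. Spearman correlations between libraries across genes were 0.966 (control and sip53), 0.965 (control and siBACH1) and 0.964 (sip53 and siBACH1).

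The BACH1 transcript was lower in the library labelled with its siRNA. BACH1 (chromosome 21, 29194071 to 29630751 on the plus strand, GRCh38, protein-coding) was at 15.2 TPM in the control, 19.6 TPM in sip53 and 4.30 TPM in siBACH1. The siBACH1 level was 28.4% of control, a log2 change of -1.61, and the sip53 level was 129% of control.

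Knockdown of p53 was compared with the control siRNA to ask which transcripts differ when p53 is lowered in these cells. The list of DNA replication genes lay below random lists. GINS2, a subunit of the replicative helicase, was lower by 1.82-fold (29.6 to 16.3 TPM), and CDT1, which loads the helicase onto origins, was lower by 1.72-fold (23.0 to 13.4 TPM). The helicase subunits MCM5 (156 to 93.6 TPM) and MCM2 (114 to 74.5 TPM) had log2 changes of -0.73 and -0.60. Of the 24 measured G1/S and DNA replication genes, 5 were at least 1.5-fold lower, 0 were at least 1.5-fold higher, and 22 had a negative log2 change. The list's median of -0.42 lay below all 10000 random lists (percentile 0.00), against a median of -0.07 over all measured genes. The 24 measured G2/M genes, which act in mitosis, had a median of -0.07 (percentile 61.9), with 0 members past 1.5-fold. Among them CDC20 was at -0.40, FOXM1 at -0.29, AURKB at -0.26 and BIRC5 at -0.23.

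Canonical p53 targets did not stand apart from random lists in the p53 knockdown library. Of 29 measured members, 1 was at least 1.5-fold higher and 1 at least 1.5-fold lower, and the median was -0.06 (percentile 56.9), a sign that turned to 0.01 after rescaling to a median ratio of 1. TIGAR, a regulator of glycolysis, had a log2 change of 0.75 (7.27 to 12.9 TPM), and the kinase PLK2 one of 0.54 (52.5 to 76.6 TPM). SPATA18 was at -0.63 and CYFIP2 at -0.42, both near 1 TPM in the control. The cell cycle inhibitor CDKN1A, at 54.7 TPM in the control and 51.7 TPM in sip53, and the p53 ubiquitin ligase MDM2, at 30.3 and 33.9 TPM, are named after their values were seen.

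Among single genes, 49 were at least 2.0-fold higher and 71 at least 2.0-fold lower of 12412 measured, or 0.967%. After correction for transcript GC content and length, chosen after seeing the data, the counts were 51 and 41. Protein-coding genes made up 25 of the higher and 29 of the lower genes. Higher protein-coding genes named by the rule included SMIM11A (log2 change 1.31), ARHGAP33 (2.70 to 7.84 TPM, 1.26), TRIM66 (1.12) and the tetraspanin TSPAN2 (1.12). Also higher were SIK1, a salt-inducible kinase (3.13 to 7.92 TPM, 1.11), and COX6B1, a subunit of cytochrome c oxidase (1.07). SMIM11B, a near-identical listed copy of SMIM11A, went from 24.0 to 17.5 TPM. The summed TPM of SMIM11A and SMIM11B was 26.6 in the control and 25.3 in sip53. Whether the other single genes named here, SIK1 among them, have such copies was not examined. Lower ones included the read-through transcript ST20-MTHFS (-1.48), LIN37, a subunit of the cell cycle repressor complex DREAM (6.81 to 2.02 TPM, -1.37), SERAC1 (-1.34), DERPC (-1.31), CTC1, part of the telomere-capping CST complex (-1.29), and the gap junction protein GJC1 (-1.25).

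The other genes named by the rule in the p53 knockdown were mostly pseudogenes and read-through transcripts, whose reads can be shared with parent genes. MRPS10P1 and the T cell receptor segment TRAJ22 were listed at 0 in the control and at 5.33 and 5.03 TPM in sip53. CDC26P1 (log2 change 2.17), BRCA1P1 (2.15), FGF7P6 (1.29) and CBWD4P (1.06) were higher. H3P6, at 30.2 TPM in the control, and SRP9P1, at 19.2 TPM, were listed at 0 in sip53. BLOC1S5-TXNDC5 (-2.03), EIF1AXP1 (-1.81) and GUSBP14 (-1.46) were lower.

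In the p53 knockdown library 7 of the 28 lists with a percentile stood apart, 4 above and 3 below. Lists of independently drawn genes would give 1.40. Members of a list can differ together and several lists share members, so 1.40 is no measure of chance here. Other NRF2-responsive genes, which serve antioxidant and pentose phosphate metabolism, had a median of 0.08 (percentile 99.97) with 0 of 19 past 1.5-fold; AKR1B1 was at -0.36, CBR1 at -0.23, TKT at -0.17 and AKR1C3 at 0.16. Hypoxia and glycolysis genes had a median of -0.18 (percentile 0.870), with 1 of 24 lower, ANKRD37 at -1.02, and PFKFB4 at -0.58. Epithelial junction genes had a median of 0.02 (percentile 98.1) with 0 of 21 past 1.5-fold, with 11 members positive and 10 negative, among them the tight junction gene CLDN1 at 0.35, the junction proteins JUP at -0.29 and CRB3 at -0.27, and the cadherin CDH1 at 0.25. Matrix proteases had a median of 0.08 (percentile 99.1), with 2 of 19 higher, ADAMTS1 at 0.69 and MMP3 at 0.65 (0.635 to 1.56 TPM), and PLAT at -0.47 and MMP10 at 0.41. Of the 19, 10 were positive and 9 negative. With a minimum of 5 TPM the protease median was -0.03 (percentile 74.2). The last 3 lists did not stand apart after the GC content and length correction, at percentiles of 8.50, 88.2 and 86.4.

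The 13 mitochondrially encoded genes, which code for respiratory chain subunits, had a median log2 change of 0.23 (percentile 100) in sip53, with all 13 positive but 0 past 1.5-fold, led by MT-ATP8 at 0.42. They took 24.8% of TPM in the control, 29.2% in sip53 and 28.2% in siBACH1. All 26 cytosolic ribosomal protein genes were negative, with a median of -0.21 (percentile 0.05) and RPS2 at -0.41, though 0 passed 1.5-fold. The log2 changes also followed transcript GC content. The Spearman correlation across genes, which are not independent replicates, was -0.40 in sip53 and -0.21 in siBACH1.

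**Figure D1:**
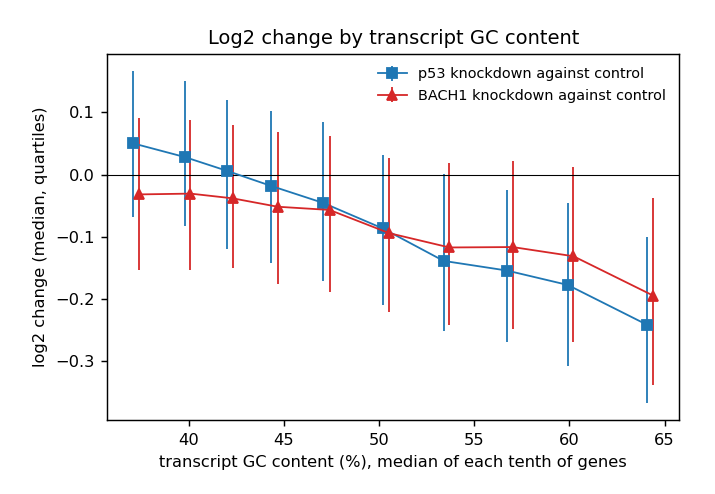
Median log2 change against control, with quartiles as bars, for the measured genes divided into equal bins by transcript GC content in percent. In the p53 knockdown (blue squares) the median was 0.05 in the bin of lowest GC content and -0.24 in the highest, and in the BACH1 knockdown (red triangles) it was -0.03 and -0.19.

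Knockdown of BACH1 was compared with the control siRNA to ask which transcripts differ when BACH1, a repressor, is lowered. HMOX1, the heme-degrading enzyme heme oxygenase 1 (chromosome 22, 35380361 to 35394214 on the plus strand), was at 4.10 TPM in the control, 4.82 TPM in sip53 and 785 TPM in siBACH1, a 192-fold higher level. FTH1, the iron-storing ferritin heavy chain (chromosome 11, 61959718 to 61967660 on the minus strand), was 3.02-fold higher (2334 to 7060 TPM). GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, was 1.83-fold higher (117 to 215 TPM), and ME1, an NADPH-producing malic enzyme, was 1.57-fold higher (39.9 to 62.5 TPM). Keratins were lower at the same time, among them KRT4 by 2.23-fold (370 to 166 TPM) and KRT14 by 2.15-fold (215 to 100.1 TPM).

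Of the 17 measured BACH1-repressed antioxidant, heme and iron genes, 4 were at least 1.5-fold higher (HMOX1, FTH1, GCLM and ME1), 0 were lower and 13 lay between. The median was 0.12 (percentile 100), against -0.08 over all measured genes. Members named after their values were seen were the heme transporter SLC48A1 (log2 change 0.38), the quinone reductase NQO1 (0.38), the thioredoxin reductase TXNRD1 (0.30), the cystine transporter SLC7A11 (0.25) and the catalytic subunit GCLC (-0.11). In the p53 knockdown 0 of the 17 passed 1.5-fold, with a median of -0.05 (percentile 68.5) that turned to 0.02 after rescaling; SLC7A11 was at -0.42, TFE3 at -0.34, FTH1 at 0.25 and GCLM at -0.21. Of 19 other NRF2-responsive genes, 1 was at least 1.5-fold higher in siBACH1. This was the aldose reductase AKR1B1 (61.3 to 115 TPM, 0.90), and the glutathione peroxidase GPX2 was at 0.39 and CBR1 at -0.37. The list's median was 0.02 (percentile 99.5, or 97.3 among random lists not matched on expression, where it no longer stood apart).

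Genes that protect from ferroptosis, a death by iron-dependent lipid peroxidation, were higher in 3 of 18 cases, namely GCH1, FTH1 and GCLM, and DHODH was at -0.32. Their median was -0.03 (percentile 81.7), or 0.05 after rescaling. In sip53 their median was -0.11 (percentile 32.4), with GCH1 at 1.45, GSS at -0.49, SLC7A11 at -0.42 and SCD at -0.31. Ferroptosis promotion genes had a median of -0.03 (percentile 73.6) in siBACH1 and of 0.00 (percentile 82.2) in sip53. The only one past 1.5-fold in either was CHAC1, an enzyme that degrades glutathione, at 7.77 TPM in the control and 0.975 TPM in siBACH1 (log2 change -2.15). LPCAT3 was at -0.41 in sip53 and -0.35 in siBACH1, and ALOX15 at 0.32 and 0.37.

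**Figure D2:**
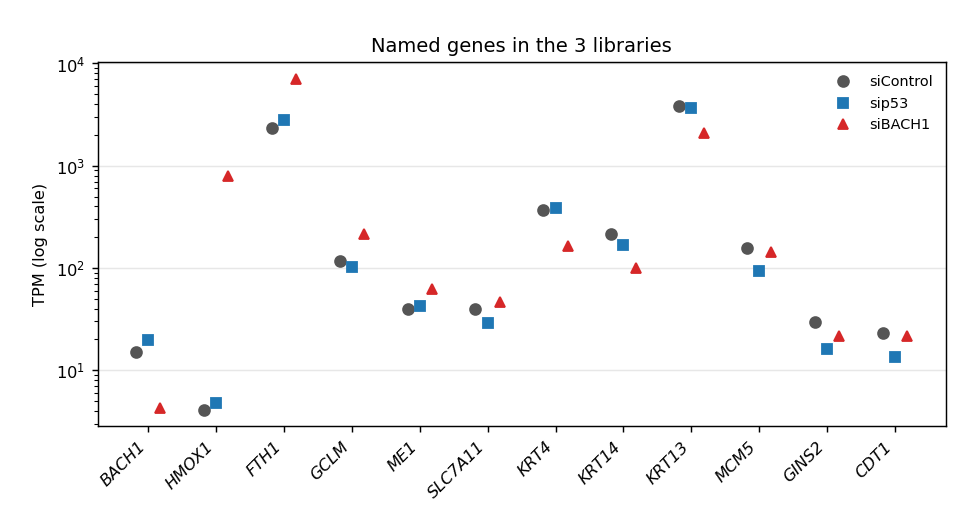
TPM on a log axis for 12 named genes in the control (grey circles), sip53 (blue squares) and siBACH1 (red triangles) libraries, 1 point per library and no error bars because each group has 1 library. HMOX1 stood at 785 TPM in siBACH1 against 4.10 and 4.82 TPM in the other libraries, and KRT4 at 166 TPM against 370 and 389 TPM.

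The squamous gene lists lay below random lists in the BACH1 knockdown library. Of 24 measured squamous differentiation genes, 9 were at least 1.5-fold lower and 0 higher, with a median of -0.33 (percentile 0.00). They included the suprabasal keratins KRT4 (-1.15), KRT16 (-1.01), KRT6A (-0.94) and KRT13 (3821 to 2087 TPM, -0.87). Of 17 basal squamous genes, 4 were at least 1.5-fold lower and 0 higher, with a median of -0.27 (percentile 0.00). These were KRT14 (-1.10), KRT17 (758 to 438 TPM, -0.79), the hemidesmosome collagen COL17A1 (-0.69) and KRT5 (4883 to 3101 TPM, -0.65). The 55 listed keratin genes, leaving out keratin pseudogenes, summed to 1.89% of TPM in the control, 1.81% in sip53 and 1.23% in siBACH1. In sip53 the medians of the differentiation and basal lists were -0.07 (percentile 55.9) and -0.04 (percentile 82.4), and both were positive after rescaling. KRT6A and KRT6B are near-identical copies, so their separate values are uncertain.

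Of 18 matrix proteases, 3 were at least 1.5-fold lower and 1 higher in siBACH1, with a median of -0.20 (percentile 1.98, or 2.74 after the GC content and length correction, where the list no longer stood apart). MMP10 (17.9 to 8.91 TPM, -0.93), the gelatinase MMP2 (-0.70) and the cathepsin CTSB (242 to 150 TPM, -0.69) were lower. Of 14 TGF-beta response genes, 2 were lower, ID2 (-0.78) and ID3 (-0.59), and 1 was higher, with LTBP2 at -0.55. The median was -0.29 (percentile 0.220). The 9 measured BACH1-linked invasion and glycolysis genes had a median of -0.22 (percentile 5.75) in siBACH1 and -0.15 (percentile 19.2) in sip53, with 0 past 1.5-fold in either library. In siBACH1 the collagenases MMP1 and MMP13 were at -0.53 and -0.46, SNAI2 at -0.42 and CDH2 at -0.24.

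Cell cycle and p53 target lists did not stand apart in siBACH1. The G1/S list had a median of -0.08 (percentile 51.8) and 0 of 24 past 1.5-fold, with CCNE1 at -0.52. The G2/M list had a median of -0.10 (percentile 25.6), with 1 of 24 lower, the cyclin CCNA2 (71.7 to 39.4 TPM, -0.85). Canonical p53 targets had a median of -0.01 (percentile 93.5) and 0 of 29 past 1.5-fold, with FAS at 0.58, PHLDA3 at -0.53, CYFIP2 at 0.51 and GDF15 at 0.49. The ATF4 stress response list had a median of -0.16 (percentile 2.16, or 4.72 after the GC content and length correction), with 1 of 22 lower, CHAC1, and SLC3A2 at -0.30, SLC7A5 at -0.29 and TRIB3 at 0.28. Epithelial junction genes had a median of -0.15 (percentile 5.21, or 0.340 after that correction), with 1 of 21 lower, the transcription factor GRHL2 at -0.62, followed by the plakophilins PKP1 (-0.58) and PKP3 (-0.43), while the claudin CLDN7 was at 0.40.

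Of 12437 measured genes, 76 were at least 2.0-fold higher and 102 at least 2.0-fold lower in siBACH1, or 1.43%. After the GC content and length correction the counts were 84 and 66. Protein-coding genes made up 46 of the higher and 59 of the lower genes. After HMOX1, the higher protein-coding genes named by the rule were PWP2 (0.248 to 6.45 TPM, log2 change 2.58), the secreted protease HTRA3 (0.597 to 7.77 TPM, 2.46), SMIM11A (2.13), FAM220A (4.18 to 17.7 TPM, 1.85), GCH1, the first enzyme of tetrahydrobiopterin synthesis (0.913 to 5.15 TPM, 1.68), the meiotic recombinase DMC1 (1.64), FTH1 (1.60) and the LIM-domain protein FHL1 (1.42). The lower ones included EIF3CL (48.9 to 7.72 TPM, -2.52), CHAC1, the chromatin remodeller INO80 (12.2 to 2.98 TPM, -1.73), BTBD6 (-1.70), BACH1, SYCE1L (-1.60), TMEM37 (-1.46) and the ubiquitin ligase UBR3 (-1.44). SMIM11A and EIF3CL have near-identical listed copies, SMIM11B (24.0 to 8.97 TPM) and EIF3C (205 to 223 TPM). Whether the other single genes named here, PWP2 among them, have such copies was not examined. The siRNA sequences were not used here, so off-target matches in lower genes such as INO80, BTBD6 and UBR3 were not searched. Among pseudogenes, HLA-Z was listed at 0 in the control and at 6.46 TPM in siBACH1, HMGB1P5 (1.54) and CYCSP24 (1.30) were higher, and SRP9P1, EIF1AXP1 and ISCA1P4 (-1.60) were lower.

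In siBACH1, 10 of the 28 lists with a percentile stood apart, 5 above and 5 below. The mitochondrially encoded genes had a median of 0.20 (percentile 100), with all 13 positive but 0 past 1.5-fold and MT-ND6 at 0.47. Cytosolic ribosomal proteins had a median of 0.02 (percentile 99.5), with RPLP1 at -0.28 and RPL11 at 0.12, and 0 of 26 past 1.5-fold. Cholesterol synthesis genes had a median of 0.05 (percentile 99.98) with 0 of 20 past 1.5-fold, among them MVD at 0.22 and HMGCS1 at 0.21, while SREBF2 was at -0.27.

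**Figure D3:**
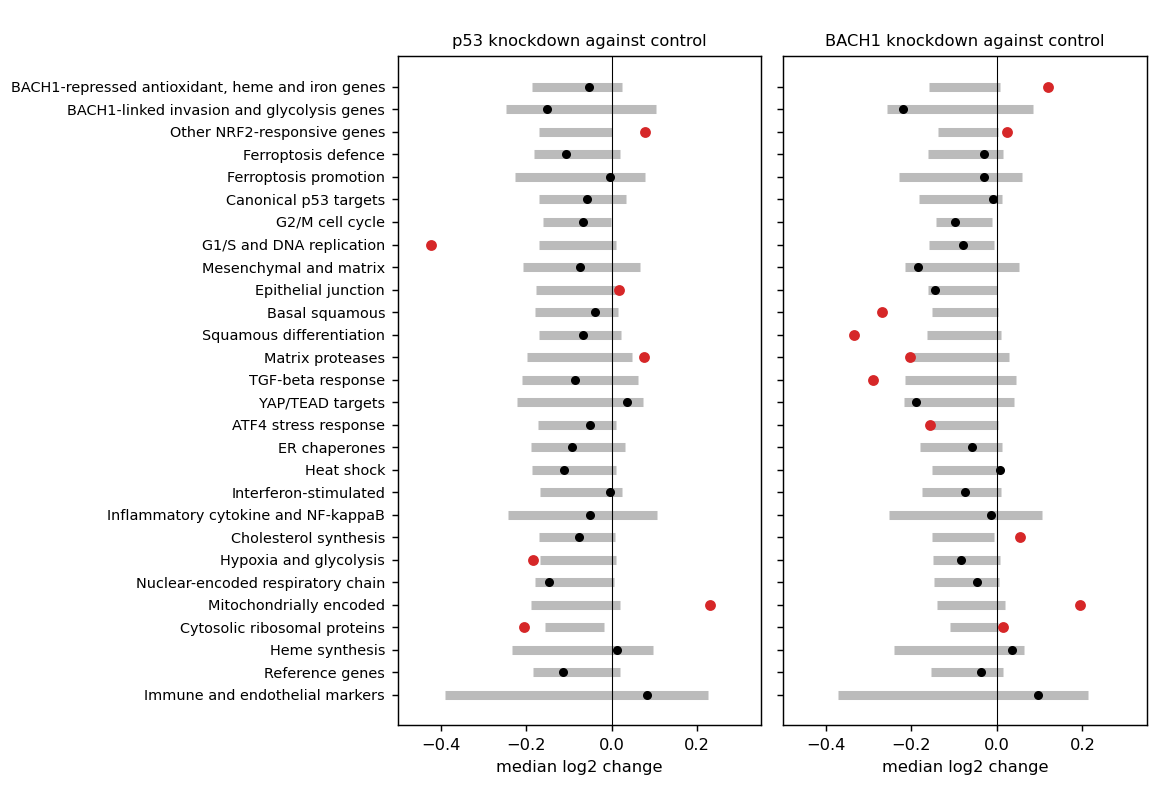
Median log2 change of 28 gene lists in each knockdown against control (points), with the central 95% of 10000 random lists matched on expression as grey bars. Red points lie outside the bars, 7 in the p53 knockdown and 10 in the BACH1 knockdown, with G1/S and DNA replication at -0.42 in the first and squamous differentiation at -0.33 in the second.

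The knockdown libraries were also compared with each other. BACH1 knockdown had 97 genes at least 2.0-fold higher and 94 at least 2.0-fold lower than p53 knockdown, of 12390 measured. Lists above random lists were BACH1-repressed genes (median 0.27), ferroptosis defence (0.18), G1/S and DNA replication (0.34), cholesterol synthesis (0.18) and cytosolic ribosomal proteins (0.21). Lists below were matrix proteases (-0.31), TGF-beta response (-0.30), YAP/TEAD targets (-0.28), basal squamous (-0.28) and squamous differentiation genes (-0.25). The other 18 lists with a percentile had medians from -0.17 to 0.13.

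Some genes differed from the control in the same direction in both knockdowns. GCH1 (log2 changes 1.45 in sip53 and 1.68 in siBACH1), PWP2 (1.34 and 2.58, from 0.248 TPM in the control) and SMIM11A were higher in both. So were the calcium-binding protein S100P (3.55 TPM in the control, 8.41 and 10.1 TPM in the knockdowns), SLC25A53 (0.94 and 0.89) and CATSPER2 (0.81 and 0.86). The pseudogenes CBWD4P and CYCSP24 were also higher in both. However, the summed TPM of SMIM11A and its copy SMIM11B was 26.6 in the control, 25.3 in sip53 and 23.5 in siBACH1. ST20-MTHFS, LIN37, the adhesion molecule ICAM5 (-0.91 and -1.09), BLOC1S5-TXNDC5 and the pseudogenes SRP9P1, EIF1AXP1, ISCA1P4 and POLR2KP1 were lower in both. In opposite directions, genes including DAPL1 (0.70 and -0.93), the serpin SERPINB3 (0.68 and -0.81), AGO4, CENPS-CORT and the carboxylesterase CES1 (0.59 and -0.68) were higher in sip53 and lower in siBACH1. The axon guidance receptor ROBO3 (-0.93 and 0.80) and the pseudogene HMGN1P8 were lower in sip53 and higher in siBACH1.

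Across 12564 genes the 2 responses had a Pearson correlation of 0.39 and a Spearman correlation of 0.37. Unchanged libraries sharing a control gave a mean Pearson correlation of 0.50 over 100 simulations, from 0.48 to 0.52. The covariance was 0.0344, against 0.0536 simulated. The simulation counts the whole difference between the knockdown libraries as noise and gives the control the same noise. Its covariance is an upper bound only if the control library is no noisier than the knockdown libraries, which was not tested. The simulated noise was normal and centred on 0, while the measured genes had median log2 changes of -0.07 in sip53 and -0.08 in siBACH1. At 2.0-fold, 12 genes were higher in both and 29 lower in both, against 9.94 and 10.2 simulated and 0.296 and 0.576 for independent lists, and 0 genes passed in opposite directions. The control is 1 library and could not be split, so part or all of the excess may come from it.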

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

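The values in this part come from lists and comparisons fixed beforehand, and the pairs were picked out by their opposite signs. Matrix proteases had a median log2 change of 0.075 in the p53 knockdown and -0.20 in the BACH1 knockdown, both against the same control library. They drew attention because the medians lie on opposite sides of random lists; the difference between the knockdowns was not tested, since each has 1 library. The positive sign in the p53 knockdown was lost with a minimum of 5 TPM, at -0.03. After the GC content and length correction, chosen after seeing the data, the list no longer stood apart in either knockdown, at percentiles of 86.4 and 2.74. Cytosolic ribosomal proteins had a median of -0.21 in the p53 knockdown and 0.015 in the BACH1 knockdown, again opposite and again not tested. In the BACH1 knockdown 16 of the 26 were positive and 10 negative, so the opposite sign is no clear rise. All 88 cytosolic ribosomal protein genes took 11.25% of TPM in the control, 9.79% in sip53 and 11.20% in siBACH1. No group held enough libraries to look for one far from the others.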

How the results depend on the processing

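The protein-coding restriction and the correction for GC content and length were chosen after seeing the data. The counts of genes past 2.0-fold depended on how weakly expressed genes were treated, as the filter, pseudocount and threshold set them by construction. The counts are given as higher and lower for p53 knockdown against control, then BACH1 knockdown against control, then BACH1 knockdown against p53 knockdown. With a pseudocount of 0.1 TPM they were 126 and 206, then 161 and 234, then 226 and 212. With a pseudocount of 5 TPM they were 4 and 4, then 8 and 16, then 14 and 14. With a minimum of 5 TPM they were 14 and 23, then 19 and 37, then 35 and 40. Without mitochondrial and ribosomal protein genes, which raises all remaining TPM, they were 104 and 124, then 152 and 154, then 173 and 157. Among protein-coding genes they were 25 and 29, then 46 and 59, then 60 and 62. At 1.5-fold they were 191 and 357, then 221 and 459, then 352 and 394, and at 3-fold 8 and 13, then 21 and 19, then 24 and 18. The GC content and length correction left 41 lower genes in the p53 knockdown and 66 in the BACH1 knockdown, and its other counts, like those under rescaling or without a filter, stayed within 1.5-fold. The correlation of the responses was 0.44 with a pseudocount of 0.1 TPM and 0.35 with a minimum of 5 TPM; the cause was not tested.

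BACH1 in its knockdown stayed between -1.79 and -1.11 under the alternatives run for it. Replication genes in the p53 knockdown, and BACH1-repressed, basal squamous and squamous differentiation genes in the BACH1 knockdown, stood apart under every alternative run for lists. Lists that lost this under 1 or more alternatives were epithelial junction, matrix proteases, and hypoxia and glycolysis in the p53 knockdown, and other NRF2-responsive genes, matrix proteases and ATF4 stress response in the BACH1 knockdown. Lists that stood apart only under an alternative were the respiratory chain in the p53 knockdown, at percentile 1.65 after the GC content and length correction, and mesenchymal (2.2), epithelial junction (0.170) and heat shock genes (98.05) in the BACH1 knockdown. Of the values of named genes under alternatives, 60 moved by 1.5-fold or more and 1816 by less. Several list medians near -0.07 turned positive when TPM was rescaled to a median ratio of 1. No paired analysis was possible because each group has 1 library. TPM keeps no depth, so counting error could not be separated from other differences in weakly expressed genes.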

Other observations

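The tests below of GC content and length, mitochondrial share, G2/M genes, keratin sums and near-identical copies were chosen after seeing the data; only for GC content and length was the outcome each explanation needs written down before the test's result was seen. Heme synthesis genes had a median log2 change of 0.03 (percentile 94.3) in the BACH1 knockdown, with 1 of 10 at least 1.5-fold higher. ALAS1, the rate-limiting first enzyme, went from 28.4 to 44.0 TPM and FECH, which inserts iron into the ring, from 21.0 to 31.5 TPM, while PPOX was at -0.54 and FLVCR1 at -0.32. In the p53 knockdown the median was 0.01 (percentile 83.4). The medians were -0.03 in both with a minimum of 5 TPM. Heat shock genes had medians of 0.01 (percentile 97.1) in the BACH1 knockdown and -0.11 (percentile 31.8) in the p53 knockdown. In the BACH1 knockdown the small heat shock proteins CRYAB (20.1 to 10.2 TPM, -0.91) and HSPB1 (3202 to 2167 TPM, -0.56) were the lowest. YAP/TEAD targets had medians of -0.19 (percentile 5.92) and 0.03 (percentile 92.8), in the same order, with CCN1 at -0.50 and F3 at 0.29 in the BACH1 knockdown. Mesenchymal and matrix genes had medians of -0.18 (percentile 6.32) and -0.07 (percentile 51.1), with FN1 at 0.60 and -0.40 and TNC at -0.44 and -0.06.

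Further lists inside the random range in both knockdowns are given as the BACH1 knockdown and then the p53 knockdown. Inflammatory cytokine and NF-kappaB genes had medians of -0.01 (percentile 74.8) and -0.05 (percentile 56.6), and the chemokine CCL20 was at -0.97 and -0.76, while SAA2 was at 0.88 and 0.16. Interferon-stimulated genes had medians of -0.07 (percentile 57.1) and 0.00 (percentile 90.3), and ISG15 was at 0.306 TPM in the control, listed at 0 in siBACH1 and at 1.20 TPM in sip53. ER chaperones had medians of -0.06 (percentile 65.0) and -0.09 (percentile 37.2), the nuclear-encoded respiratory chain -0.05 (percentile 70.7) and -0.15 (percentile 10.5), and reference genes -0.04 (percentile 71.2) and -0.11 (percentile 29.4). In the p53 knockdown, cholesterol synthesis genes were at -0.08 (percentile 51.3), ATF4 stress response genes at -0.05 (percentile 72.8) and TGF-beta response genes at -0.09 (percentile 42.9). In the BACH1 knockdown, hypoxia and glycolysis genes were at -0.08 (percentile 30.6). Immune and endothelial markers, 5 of them measured, had medians of 0.10 (percentile 90.5) and 0.08 (percentile 85.6), with CD68 at 35.7 TPM and CDH5 at 16.0 TPM in the control. Of the fibroblast markers, 3 and 2 were measured, COL1A1 at 3.68 TPM in the control among them, and DCN was at 0.77 in the BACH1 knockdown. Pseudogenes were 3.73% of the genes measured in the p53 comparison and 50.8% of those past 2.0-fold, and 3.84% and 39.3% in the BACH1 comparison.

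The lower replication genes in the p53 knockdown were set against 3 explanations. After correction for GC content and length the G1/S median was -0.36, still below all random lists, which argues against sequence bias as the whole cause. Leaving out mitochondrial and ribosomal protein genes, to remove their larger share, moved it only to -0.37. That step multiplies all other genes of a library by the same factor, so it shows only how far the share could shift the median. Fewer dividing cells would lower G2/M genes alike, yet their lower quartile was -0.12, above the G1/S median of -0.42. That speaks only against a fall of like size in both lists. Whether a smaller fall in dividing cells took part was not tested. An effect of p53 knockdown and a difference between single cultures both stay open and untested, since each group is 1 library.

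The lower squamous genes in the BACH1 knockdown were examined in the same way. The squamous differentiation median was -0.25 after correction for GC content and length and -0.27 without mitochondrial and ribosomal protein genes, so neither accounts for the whole of it. For the keratins, reads moved among the 55 keratin genes would leave their sum in place, but their summed TPM had a log2 change of -0.62. Keratin pseudogenes were not part of this sum, so it cannot speak to reads moved to them. An effect of BACH1 knockdown and a difference between single cultures both stay open and untested, for the same reason.

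Some of the largest differences may come from reads divided between near-identical copies. SMIM11A was at 2.57 TPM in the control and 14.6 TPM in the BACH1 knockdown, while its copy SMIM11B went from 24.0 to 8.97 TPM. The log2 change of SMIM11B was -1.33, in the direction that read division predicts and beyond the SD of 0.31 over all measured genes, though real opposite differences would look alike. For EIF3CL (48.9 to 7.72 TPM), the test decides nothing. Its whole TPM difference would move EIF3C by only 0.26, less than that SD, and EIF3C was at 0.12.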
